A study of Rattus norvegicus with 35 samples.

How the data were processed

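Gene expression was measured in primary rat hepatocytes, liver cells isolated from the animal and kept in culture, after 72 h of exposure through the medium. Total RNA was copied into biotin-labelled cRNA and hybridized to Affymetrix rat expression arrays, on which a probe set reports the transcripts of a gene or of several close relatives. The value table held 31099 probe sets, 57 of them control probe sets, and 35 arrays in 12 groups. Each array carried 1 of 3 codes in its label (Rs256, Rs293 or Rs304). The labels do not say what the code marks, and every group held at most 1 array per code.

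The deposited values were a score on a log-like scale. The authors stated neither its base nor how probes were summarised, corrected for background or normalized. In the values, array medians lay between -0.03 and 0.02 and array SDs between 0.645 and 0.937, so the arrays shared a centre but not a spread. The control transcripts bioC, bioD and cre, which the manufacturer adds at known concentrations, rose by 0.57 to 1.15 units per natural-log step over arrays (median 0.7) if they were added at the standard concentrations of 5, 25 and 100 pM. After the quantile normalization described next the mean slope was 0.703 (SD 0.0347 over arrays). These slopes excluded a base of 10 and left a natural log or a base of 2 open, so changes are given in units of the deposited scale and not as folds. On the same assumption a doubling corresponded to 0.487 normalized units.

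Arrays were brought to a common distribution by quantile normalization. The design fixed before the data were examined named values on a log2 scale to be used as deposited, with quantile normalization as an alternative. Normalization became the main setting once the unequal array SDs and the group means of a few probe sets had been seen, and before any test was run. This choice raised the counts of called genes several times, so the counts on the values as deposited stand beside the main ones. Quantile normalization holds the brightest probe set of every array at one value: Alb, albumin, was fixed at a change of 0.00 and was not measured here.

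Probe sets were named from the annotation table of the platform. It named 1 gene for 20826 probe sets, several genes for 436 and no gene for 9780, and the gene identifier of 20758 probe sets matched the reference gene table. A feature was a gene, represented by the probe set with the highest mean over all arrays among those naming that gene alone. A gene was tested if its value lay above the array's median in at least 2 of 35 arrays, which kept 10490 of 14217 genes. The array files name no genome build, so no coordinates are given.

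Comparisons used limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 35 arrays, 1 mean per group and no covariate. All groups shared 1 residual spread per gene. Contrasts were each treatment against DMSO (11), each pair of triazoles at the same dose (9) and the slope on log10 dose over 10, 30 and 100 uM within each triazole (3). A gene was called when its p, adjusted by Benjamini and Hochberg within the comparison, lay below 0.05, with no minimum change. Tests were two-sided. Errors are standard errors of the fit (SE) or standard deviations between arrays (SD), and the number of arrays limits the precision of every value.

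The Rs code entered as a fixed replicate block in an alternative fit. After group means were removed, arrays of the same code correlated across genes at r between 0.277 and 0.953 in the groups compared, and over all 187 same-code pairs the median was 0.634, against -0.355 for pairs of different codes. The 1st principal component held 40.6% of the variance and parted Rs256 from the other codes. No protocol states a paired test, so the unblocked fit stayed the main one and the blocked values stand beside it. By chance alone about 524 genes would have an unadjusted p under 0.05 in a comparison. In the unblocked fit 21 did for myclobutanil at 10 uM and 96 for phenobarbital, and with the block 61 and 437. The unblocked fit was thus conservative in such comparisons, and a low count there does not show a lack of effect.

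Before the real comparisons the fit was tested on simulated data for 5 of them, with 100 genes changed by 0.5 units and 100 by 1 unit among 10490. For propiconazole at 100 uM it recovered 91% and 100% of these genes with 0 false calls, and with the replicate block 96% and 100% with 6 false calls. For myclobutanil at 100 uM it recovered 88% and 99% with 3 false calls, and for phenobarbital 90% and 95% with 2. For PCN it recovered 89% and 100% with 0, and for the propiconazole slope 89% and 97% with 1. With the block these 4 gave 95% to 98% and 100%, with 9 to 14 false calls. Each simulation held 200 changed genes, whereas the real unblocked fits called 1 gene for phenobarbital and 1 for PCN. In those fits Cyp3a23-3a1 changed by 0.68 (SE 0.178) with phenobarbital and by 0.58 (SE 0.199) with PCN and was not called. The simulated rates thus do not give the share of real changes of these sizes found in comparisons with few calls.

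Before the data were examined, 22 gene lists were fixed: targets of the receptors CAR, PXR, AhR and PPARalpha, sterol synthesis, fatty acid synthesis, bile acid synthesis and transport, NRF2 targets, phase II conjugation, endoplasmic reticulum stress, p53 targets, cell cycle, hepatocyte function, steroid metabolism, retinoid metabolism, acute phase, ribosomal proteins, mitochondrial respiration and markers of 4 other liver cell types. Of 469 entries 394 matched a gene on the array. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the 22 lists. A further 7 lists were added after some of the named genes had been seen and were tested in a family of their own. Named genes followed a rule fixed in advance: 6 anchor genes, of which Cyp2b1 had no probe set of its own, up to 3 called members per list, and the 5 largest rises and falls with the same sign in every Rs code. For triazole pairs and slopes it took the 5 largest differences each way, and for lower doses the same genes. Genes outside the rule were chosen after their values were seen.

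Overlaps of called genes were set beside the overlap of independent lists, and correlations across genes beside 100 simulated pairs of unchanged groups that shared the 3 DMSO arrays, which are too few to split. The Actb and Gapdh control probe sets gave a 3 prime minus 5 prime difference per array, compared by a two-sided exact permutation test. Alternatives were the replicate block, values as deposited, centring on array medians, 2 other filters, 2 other ways to treat probe sets, fits of only the groups compared, eBayes with trend and robust on, estimated correlation, and each Rs code or array left out in turn. The values as deposited were the main setting in the design and count as planned. Fits without the Rs293 arrays labelled phenobarbital and PCN, and the block on the values as deposited, were added after seeing the data. Other splits of the same arrays were counted, all 10 for 3 arrays against 3 and 100 for each slope. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots. All 35 arrays were used.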

Results

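Primary rat hepatocytes were exposed for 72 h to 1 of 3 triazole fungicides, myclobutanil, propiconazole or triadimefon, at 10, 30 or 100 uM, to phenobarbital at 200 uM, to PCN at 30 uM, or to the vehicle DMSO at 0.1%. Triazole fungicides act on the fungal sterol demethylase Cyp51, which mammals also carry. Beside the triazole ring, myclobutanil carries a nitrile group, propiconazole a dioxolane ring and triadimefon a ketone. Phenobarbital and PCN served as the positive controls of the series, and phenobarbital is a classical inducer of liver drug metabolism through the receptor CAR. Each group held 3 arrays, 1 from each of the codes Rs256, Rs293 and Rs304, except PCN, which held 2 (Rs293 and Rs304). The comparisons asked which genes each compound changed against DMSO, how the changes went with dose, and where the triazoles differed from each other. Changes are in units of the deposited log scale after quantile normalization.

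Propiconazole at 100 uM lowered genes of fatty acid oxidation and raised genes of sterol synthesis and the desaturases Scd2, Fads2 and Fads1. Of 21 measured targets of PPARalpha, the receptor that drives fatty acid breakdown in liver, 16 fell (18 adjusted over the list alone), with a list median of -0.94 (adjusted p = 6.22e-19, and adjusted p = 0.00588 with an estimated correlation). Cyp4a3 and Cyp4a1, which hydroxylate fatty acids, fell by 2.01 (SE 0.172, n = 3 and 3, adjusted p = 1.74e-08) and by 1.91 (SE 0.350, adjusted p = 0.000515), and Angptl4, an inhibitor of lipoprotein lipase, fell by 1.86. Eci1, a mitochondrial enzyme of the same breakdown pathway, fell by 1.54 and the carboxylesterase Ces1d fell by 1.73. Each of these 5 genes was lower in all 3 Rs codes, but the rule for the largest falls, which named them, required this, so it is no separate support.

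Sterol synthesis moved the other way: 14 of 20 measured members rose (15 adjusted over the list alone) and the list median was 0.42 (adjusted p = 2.04e-09, and adjusted p = 0.0211 with an estimated correlation, or adjusted p = 0.11 with an estimated correlation in the fit with the replicate block). Acat2, which makes acetoacetyl-CoA at the entry of the pathway, rose by 0.83 (SE 0.0635, adjusted p = 9.17e-09), Cyp51 by 0.53 (adjusted p = 0.00192) and Tm7sf2 by 0.52. The desaturases Scd2, Fads2 and Fads1 rose by 2.01, 0.72 and 0.71, while the fatty acid synthesis list as a whole was not called (4 members rose and 1 fell, 5 and 2 adjusted over the list alone, adjusted p = 0.24). Scd2 lies outside the list and was named by the size of its rise, as were the fatty acid binding protein Fabp5 (1.47), the cell cycle inhibitor Sfn (1.35) and Gstk1 (1.27).

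NRF2 targets, which defend against oxidants, had 8 of 18 members raised (11 adjusted over the list alone), among them Gstp1 (1.22, SE 0.276), Akr1b8 (0.89) and Nqo1 (0.78). The list median was 0.50, and its call (adjusted p = 6.09e-06) was lost with an estimated correlation (adjusted p = 0.153) but held with both that and the replicate block (adjusted p = 0.0158). Of the endoplasmic reticulum stress list 4 of 27 members rose (7 rose and 1 fell adjusted over the list alone), led by Ddit3 at 0.76, Sdf2l1 at 0.61 and Trib3 at 0.40 (list adjusted p = 0.0458, and adjusted p = 0.303 with an estimated correlation). AhR targets rose as a list at adjusted p = 0.0458, also lost with an estimated correlation (adjusted p = 0.303). Nqo1, Tiparp and Cyp1b1 rose (3 of 7 members, and 3 adjusted over the list alone), while Cyp1a1, the most responsive AhR target, changed by 0.14 (SE 0.116, adjusted p = 0.518).

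Some genes of hepatocyte function and bile acid metabolism fell, while their lists were called only with the preset correlation. Of 25 hepatocyte function genes, 1 of which (Alb) the normalization fixed, 8 fell (8 fell and 1 rose adjusted over the list alone), including Cyp2d3 (-1.01), the gluconeogenic enzyme Fbp1 (-0.77) and Cyp2c11 (-0.54), and the list call (median -0.15, adjusted p = 0.000679) was lost with an estimated correlation (adjusted p = 0.303). Among 15 genes of bile acid synthesis and transport 5 fell and 1 rose (7 and 1 adjusted over the list alone), with Slc27a5 at -1.24 and Baat, which conjugates bile acids, at -1.19 (list adjusted p = 0.00346, and adjusted p = 0.114 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -0.07 (SE 0.254, adjusted p = 0.923). The steroid metabolism list fell (5 of 17 members, and 5 adjusted over the list alone, adjusted p = 0.0376) and the ribosomal protein list rose (1 of 13, and 1 adjusted over the list alone, adjusted p = 0.0458); both calls were lost with an estimated correlation (adjusted p = 0.303 for each), and after median centring the ribosomal test turned to lower at a list mean of 0.06. In drug metabolism Cyp2c6v1 (1.31), Cyp3a23-3a1 (0.79) and the transporter Abcc2 (0.95) rose and Sult1a1 fell by 0.86. PXR targets were not called as a list (3 rose and 1 fell, 4 and 1 adjusted over the list alone, adjusted p = 0.24), nor were CAR targets (1 rose and 2 fell, also 1 and 2 adjusted over the list alone, adjusted p = 0.819), mitochondrial respiration (adjusted p = 0.0507) or retinoid metabolism (adjusted p = 0.0953).

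Over all 10490 genes, propiconazole at 100 uM raised 668 and lowered 587 (1255 in all). With the replicate block the counts were 1644 and 1431, and on the values as deposited 250 and 178, all of them among the 1255. They were 315 and 186 after median centring, 243 and 299 when only the 2 groups compared were fitted, and 1040 and 994 with each probe set as a feature. The total was 391 without the Rs304 arrays, 732 without Rs293 and 811 without the DMSO array of Rs293. Of 46 named genes called, 21 remained called on the values as deposited and 21 in all 3 fits that left out an Rs code; 15 passed all 4, among them Cyp4a3, Cyp4a1, Angptl4, Eci1, Ces1d, Acat2, Scd2, Fads2, Sfn and Ddit3.

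**Figure D1:**
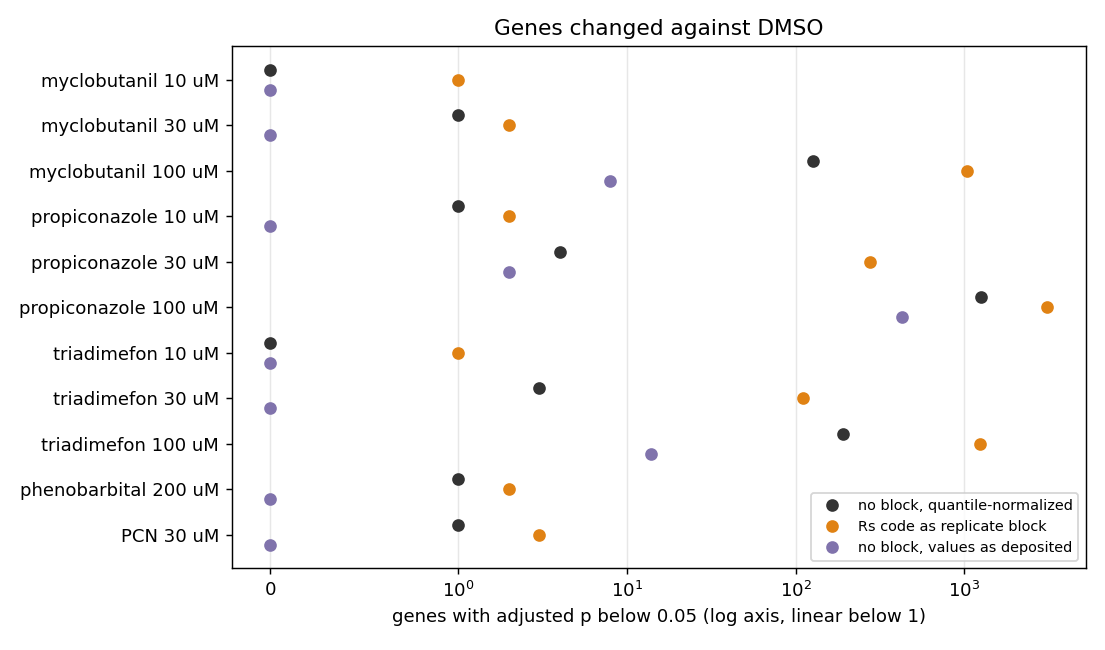
Genes called against DMSO per treatment (x axis: number of genes with adjusted p below 0.05, log axis, linear below 1), in the fit without a block, with the Rs code as replicate block, and on the values as deposited. Propiconazole at 100 uM has the highest count in each fit: 1255, 3075 and 428 genes.

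Myclobutanil at 100 uM lowered PPARalpha targets and raised sterol synthesis genes as well. Of the 21 PPARalpha targets 5 fell (13 adjusted over the list alone), with a list median of -0.58 (adjusted p = 2.84e-19, and adjusted p = 0.00267 with an estimated correlation). Cyp4a1 fell by 1.48 (SE 0.350, n = 3 and 3, adjusted p = 0.0337), Cyp4a3 by 1.21 (SE 0.172, adjusted p = 0.000358) and Fabp1, the liver fatty acid binding protein, by 1.11. Of the 20 sterol synthesis genes 7 rose (14 adjusted over the list alone; median 0.34, adjusted p = 1.25e-16, and adjusted p = 0.00213 with an estimated correlation), with Acat2 at 0.61 (adjusted p = 7.05e-06), Insig1 at 0.49 and Cyp51 at 0.44. Scd2 rose by 1.74 and Ces1d fell by 1.56.

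Genes of drug metabolism that rose with myclobutanil were Cyp2c6v1 (1.42), Abcc2 (0.95), Cyp3a23-3a1 (0.91, SE 0.178, adjusted p = 0.0113) and the glucuronosyltransferase Ugt2b1 (0.73, adjusted p = 0.000358), while Aldh1a1 fell by 0.56. The PXR target list rose (2 of 9 members rose and 1 fell, 4 and 1 adjusted over the list alone, adjusted p = 0.00659) but not with an estimated correlation (adjusted p = 0.176). The same held for fatty acid synthesis (1 of 18 rose, 5 adjusted over the list alone, adjusted p = 0.000122 and adjusted p = 0.112 with an estimated correlation) and for NRF2 targets (2 of 18 rose, 3 adjusted over the list alone, adjusted p = 0.00424 and adjusted p = 0.407 with an estimated correlation). It also held for the endoplasmic reticulum stress list (0 of 27, and 0 adjusted over the list alone), at adjusted p = 0.000689 and adjusted p = 0.126 with an estimated correlation. Hepatocyte function (3 members adjusted over the list alone, adjusted p = 0.00658), mitochondrial respiration (0, adjusted p = 0.00659) and retinoid metabolism (2, adjusted p = 0.0377) were called lower, with adjusted p = 0.423, adjusted p = 0.409 and adjusted p = 0.409 with an estimated correlation. Not called were the CAR (adjusted p = 0.0665), bile acid (adjusted p = 0.0773), ribosomal protein (adjusted p = 0.133), AhR (adjusted p = 0.825) and steroid lists (adjusted p = 0.878).

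Myclobutanil at 100 uM raised 67 genes and lowered 60 (127 in all), and 530 and 511 with the replicate block. On the values as deposited 4 rose and 4 fell, all among the 127, and after median centring 5 and 4. When only the 2 groups compared were fitted, limma called 1 of the 127 (877 genes at an unadjusted p under 0.05). Leaving out a single code or array lowered the total as far as 16 (Rs304) and 27 (the DMSO array of Rs293); it was 47 without Rs293, 45 and 44 without the DMSO arrays of Rs256 and Rs304, and 56, 38 and 53 without the myclobutanil arrays of Rs293, Rs256 and Rs304. Of 19 named genes called, Ces1d, Scd2, Cyp4a3 and Acat2 remained called on the values as deposited, and Ugt2b1, Cyp4a3 and Acat2 without each Rs code.

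Triadimefon at 100 uM raised desaturases and sterol synthesis genes and lowered PPARalpha targets. Scd2 rose by 2.08 (SE 0.299, n = 3 and 3, adjusted p = 0.000631), the lipase-like Pnpla3 by 0.92, Fads2 by 0.85 (adjusted p = 3.76e-05) and Fads1 by 0.85. The fatty acid synthesis list had 3 of 18 members raised (8 adjusted over the list alone; median 0.20, adjusted p = 1.01e-05); its call was lost with an estimated correlation (adjusted p = 0.0565) and held when the replicate block was added (adjusted p = 0.0253). Of 20 sterol synthesis genes 5 rose (13 adjusted over the list alone; median 0.27, adjusted p = 1.77e-12, and adjusted p = 0.00952 with an estimated correlation), with Acat2 at 0.65, Insig1 at 0.51 and Mvd at 0.40, while Cyp51 stood at 0.36 (adjusted p = 0.103, and 0.0111 with the replicate block). Of the 21 PPARalpha targets Angptl4 (-0.94), Cyp4a3 (-0.94, SE 0.172, adjusted p = 0.00495) and Fgf21 (-0.75) fell (6 adjusted over the list alone; median -0.37, adjusted p = 5.22e-12, and adjusted p = 0.0293 with an estimated correlation).

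Cyp2c6v1 (1.27), Abcc2 (0.91), Cyp3a23-3a1 (0.90, adjusted p = 0.0081) and Ugt2b1 (0.56) rose with triadimefon, and so did the chemokine Cxcl9 (1.24). Ces1d fell by 1.52 and Baat by 0.76. Haptoglobin, Hp, fell by 0.17 (adjusted p = 0.0435), but its change was 0.03 on the values as deposited and 0.02 after median centring. Lists called only with the preset correlation were PXR targets (2 of 9 rose, 4 rose and 1 fell adjusted over the list alone, adjusted p = 0.0123), NRF2 targets (2 of 18 rose, 4 adjusted over the list alone, adjusted p = 1.01e-05) and the lower lists of bile acid genes (3 of 15 fell and 1 rose, also 3 and 1 adjusted over the list alone, adjusted p = 0.00128), hepatocyte function (3 of 25 fell, 7 adjusted over the list alone, adjusted p = 4.12e-05), retinoid metabolism (1 of 19 fell, 4 adjusted over the list alone, adjusted p = 0.00327) and mitochondrial respiration (0 of 23, adjusted p = 0.00578). With an estimated correlation these gave, in the same order, adjusted p = 0.173, adjusted p = 0.144, adjusted p = 0.058, adjusted p = 0.173, adjusted p = 0.173 and adjusted p = 0.335. NRF2 targets were called again with both an estimated correlation and the replicate block (adjusted p = 0.0253). Not called were the CAR (adjusted p = 0.588), AhR (adjusted p = 0.7), endoplasmic reticulum stress (adjusted p = 0.0642), steroid and ribosomal protein lists (adjusted p = 0.387 each).

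Triadimefon at 100 uM raised 91 genes and lowered 101 (192 in all), and 646 and 593 with the replicate block. On the values as deposited 8 rose and 6 fell, all among the 192, and after median centring 10 rose and 7 fell. When only the 2 groups compared were fitted, limma called 10 (1467 at an unadjusted p under 0.05). The total was 11 without Rs304, 62 without Rs293 and 108 without Rs256. It was 85, 73 and 81 without the DMSO arrays of Rs256, Rs293 and Rs304, and 61, 123 and 78 without the triadimefon arrays of the same codes. Of 27 named genes called, Fads2, Ces1d, Scd2 and Acat2 remained called on the values as deposited and in all 3 fits that left out an Rs code.

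**Figure D2:**
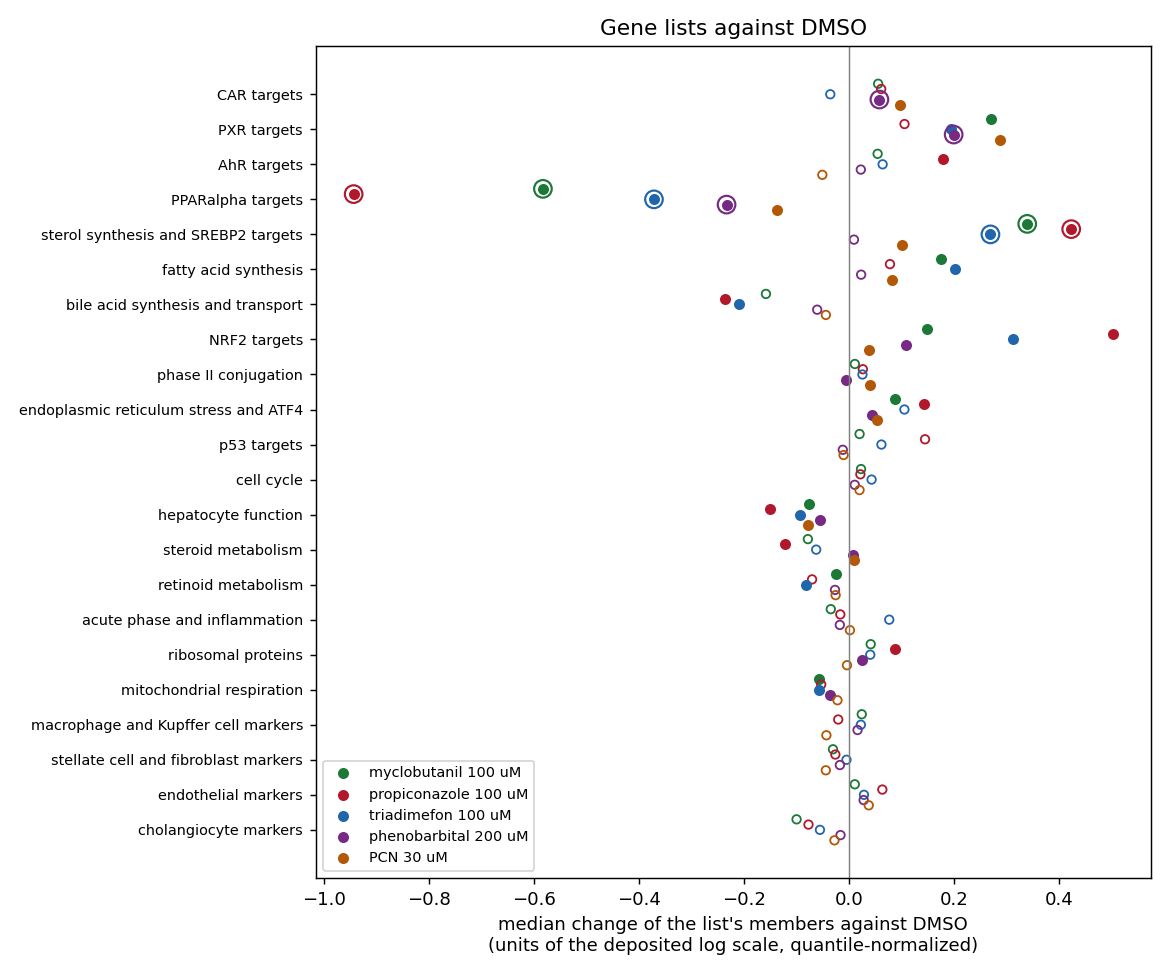
Median change of each list's measured members against DMSO (x axis, units of the deposited log scale after quantile normalization), 1 row of points per list and 1 colour per treatment. Filled points passed the list test with the preset correlation and ringed points also passed with an estimated correlation; the PPARalpha list lies lowest, at -0.94 for propiconazole at 100 uM.

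Cell type and RNA quality measures stood beside these changes as follows. Markers of stellate cells, endothelium and cholangiocytes were not called as lists for any triazole at 100 uM with limma's camera, nor were macrophage markers. Of the fixed markers 12 of 19 (stellate cell), 3 of 15 (endothelium), 6 of 11 (cholangiocyte) and 9 of 18 (macrophage) were tested. With so few genes the lack of a call does not show a lack of change. A single member, the macrophage and lysosomal gene Cd68, rose by 0.80 with propiconazole (SE 0.198, adjusted p = 0.00727), while the macrophage list had a median of -0.02, a mean of 0.10 and adjusted p = 0.927. The p53 target, cell cycle, acute phase and phase II conjugation lists were not called for any triazole at 100 uM. Of the cell cycle list 13 of 30 genes were tested. With propiconazole Tp53inp1, of the p53 list, rose by 0.31 and Ccne1, of the cell cycle list, by 0.15. Adjusted p values in the order myclobutanil, propiconazole, triadimefon were 0.943, 0.141 and 0.603 for p53 targets, 0.447, 0.24 and 0.147 for cell cycle, 0.398, 0.24 and 0.99 for acute phase and 0.943, 0.682 and 0.826 for phase II conjugation. Those of the markers were 0.856, 0.927 and 0.958 (macrophage), 0.399, 0.682 and 0.571 (stellate cell), 0.878, 0.865 and 0.387 (endothelium) and 0.195, 0.766 and 0.387 (cholangiocyte). With propiconazole the median, the mean and the test direction did not share a sign for CAR targets (0.06, 0.08, lower), phase II conjugation (0.03, 0.06, lower), acute phase (-0.02, 0.00, lower), macrophage markers (-0.02, 0.10, lower) and cholangiocyte markers (-0.08, 0.00, lower). The same held for phase II conjugation with myclobutanil (0.01, 0.05, lower) and CAR targets with triadimefon (-0.04, 0.11, higher). The Actb 3 prime minus 5 prime difference was -0.12 against DMSO in propiconazole at 100 uM, -0.04 in myclobutanil and 0.09 in triadimefon. These gave an exact permutation p of 0.1, 0.7 and 0.4, and 3 arrays against 3 cannot give less than 0.1. The Gapdh difference was -0.00, 0.01 and 0.07 in the same order (exact p of 1, 1 and 0.2). In PCN the Actb difference was -0.17 (exact p of 0.1, the smallest possible) and the Gapdh difference -0.06 (0.2), and in phenobarbital they were -0.10 (0.3) and -0.05 (0.4).

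At lower doses a few genes of drug metabolism and of lipid metabolism passed the test. Ugt2b1 rose by 0.60 at 10 uM propiconazole and by 0.78 at 30 uM, by 0.73 at 30 uM myclobutanil and by 0.65 at 30 uM triadimefon. At 100 uM propiconazole the change of Ugt2b1 was 0.18 (adjusted p = 0.265); its propiconazole dose slope was -0.43 (adjusted p = 0.00579), and it was higher with myclobutanil at 100 uM by 0.54 (adjusted p = 0.00649). At 30 uM propiconazole Cyp3a23-3a1 rose by 0.94 and Acat2 by 0.38, and Cyp4a3 fell by 0.90; at 30 uM triadimefon Scd2 rose by 1.73 and Acat2 by 0.37. With the replicate block Cyp2c6v1 was called at every dose of every triazole, at 10 uM by 0.89 with myclobutanil, 1.26 with propiconazole and 0.84 with triadimefon. At 30 uM the PPARalpha list was lower for myclobutanil (median -0.24, adjusted p = 0.0139 with an estimated correlation), propiconazole (-0.37, adjusted p = 0.0114) and triadimefon (-0.31, adjusted p = 0.0259), and sterol synthesis was higher for propiconazole (0.20, adjusted p = 0.00776) and triadimefon (0.25, adjusted p = 0.000644). PXR targets were higher at 30 uM for myclobutanil (0.39, adjusted p = 0.0236) and triadimefon (0.28, adjusted p = 0.0408). At 10 uM triadimefon alone had lists called with an estimated correlation, PPARalpha targets (-0.25, adjusted p = 0.0436) and sterol synthesis (0.16, adjusted p = 0.00262). Other lists called with the preset correlation were lost with an estimated one. For myclobutanil these were 4 at 10 uM (adjusted p between 0.295 and 0.375) and 7 at 30 uM (between 0.136 and 0.496), for propiconazole 8 (0.0771 to 0.492) and 8 (0.0839 to 0.524), and for triadimefon 8 (0.0765 to 0.506) and 7 (0.164 to 0.322). Adding the replicate block to the estimated correlation called PXR targets at 30 uM propiconazole (adjusted p = 0.0433) and 10 uM triadimefon (adjusted p = 0.0468). It also called NRF2 targets at 30 uM triadimefon (adjusted p = 0.0163).

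Genes called at 30 uM numbered 1 for myclobutanil, 4 for propiconazole and 3 for triadimefon, and 2, 275 and 110 with the replicate block. Leaving out the Rs293 arrays labelled phenobarbital and PCN raised the propiconazole and triadimefon counts at 30 uM several times, as given below. At 10 uM limma called 1 gene for propiconazole and 0 for myclobutanil and triadimefon. For the latter 2 compounds 21 and 130 of 10490 genes had an unadjusted p under 0.05, where chance alone would give about 524. With the replicate block limma called 2, 1 and 1. On the values as deposited, and after median centring, 2 genes were called at 30 uM propiconazole and 0 in the other groups at 10 and 30 uM. Fitting only the 2 groups compared left 1 gene at 30 uM propiconazole; limma called 0 at 30 uM myclobutanil and triadimefon and at 10 uM propiconazole, with 122, 562 and 291 at an unadjusted p under 0.05. With each probe set as a feature 2 were called at 30 uM propiconazole and 5 at 30 uM triadimefon, and without a filter 2 at 30 uM propiconazole. Without Rs304 the counts of 1, 4 and 3 at 30 uM and of 1 at 10 uM all became 0. At 30 uM propiconazole the 4 became 1 without the DMSO array of Rs293 or Rs304 or its own array of Rs304, and 2 without the DMSO array of Rs256 or its own of Rs256 or Rs293. At 30 uM triadimefon the 3 became 0 without the DMSO or the triadimefon array of Rs293, and 1 without Rs256, its own array of Rs256 or the DMSO array of Rs304. The 1 of myclobutanil became 0 without Rs293 and 2 without Rs256 or its DMSO array, and the 1 of 10 uM propiconazole became 0 without any code or any of its own arrays.

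Dose slopes within each triazole showed which genes had a linear trend on log10 dose from 10 to 100 uM. A slope does not tell a graded change from a step at 100 uM. With propiconazole at 10, 30 and 100 uM, Cyp4a3 changed against DMSO by -0.41, -0.90 and -2.01. Gstp1 changed by -0.01, -0.14 and 1.22, and Sfn by 0.06, 0.15 and 1.35. With propiconazole Cyp4a3 fell by 1.61 units per log10 step of dose (SE 0.172, adjusted p = 1.01e-06), Angptl4 by 1.56, Cyp4a1 by 1.36 and Eci1 by 1.29, and Sfn rose by 1.30, Gstp1 by 1.25 and Fabp5 by 1.16. With myclobutanil Acat2 rose by 0.63 (SE 0.0635, adjusted p = 2.9e-06), Scd2 by 1.51 and Insig1 by 0.49, and Ces1d fell by 1.16 and Cyp4a3 by 0.99. With triadimefon Fabp5 rose by 0.82, Fads2 by 0.67 (adjusted p = 0.00585) and Acat2 by 0.39. The PPARalpha list had negative slopes for propiconazole (10 of 21 members, 14 adjusted over the list alone; median -0.52, adjusted p = 0.0275 with an estimated correlation) and for myclobutanil (2 of 21, 5 adjusted over the list alone; -0.40, adjusted p = 0.0211), and for triadimefon the call at the preset correlation (median -0.12, adjusted p = 7.08e-05) was lost (adjusted p = 0.277). Sterol synthesis (4 of 20 members, 16 adjusted over the list alone; 0.34, adjusted p = 0.000616 with an estimated correlation) and fatty acid synthesis (0.19, adjusted p = 0.0473) had positive slopes for myclobutanil. For propiconazole sterol synthesis (8 of 20, 12 rose and 1 fell adjusted over the list alone) was lost at adjusted p = 0.0849, NRF2 targets at adjusted p = 0.167 and 7 more lists at adjusted p between 0.121 and 0.248. NRF2 targets were called again with both an estimated correlation and the replicate block (adjusted p = 0.0393). For myclobutanil the lists lost were endoplasmic reticulum stress (adjusted p = 0.102), NRF2 targets and cholangiocyte markers (adjusted p = 0.597 each) and mitochondrial respiration (adjusted p = 0.649), and for triadimefon 7 more lists, at adjusted p between 0.277 and 0.349.

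In all, 526 genes rose and 390 fell with propiconazole dose, 15 rose and 11 fell with myclobutanil and 7 rose and 1 fell with triadimefon. Under the replicate block these were 1399 and 1203, 374 and 322, and 161 and 146, and on the values as deposited 151 and 113, 1 and 1, and 0. Median centring gave 165 and 114, 1 and 1, and 0. When only the 3 doses of a compound were fitted, limma called 365 for propiconazole, 0 for myclobutanil (705 at an unadjusted p under 0.05) and 6 for triadimefon. With each probe set as a feature the propiconazole total was 1427. Without Rs304 the totals of 916, 26 and 8 became 206, 1 and 0. For propiconazole the total was 421 without Rs293 and 519 without the 10 uM array of Rs293. For myclobutanil it was 89 without Rs256, 17 without Rs293, 5 without the 10 uM array of Rs304, and 8 and 13 without the 100 uM arrays of Rs256 and Rs293. For triadimefon it lay between 0 and 5 without any 1 code or array.

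**Figure D3:**
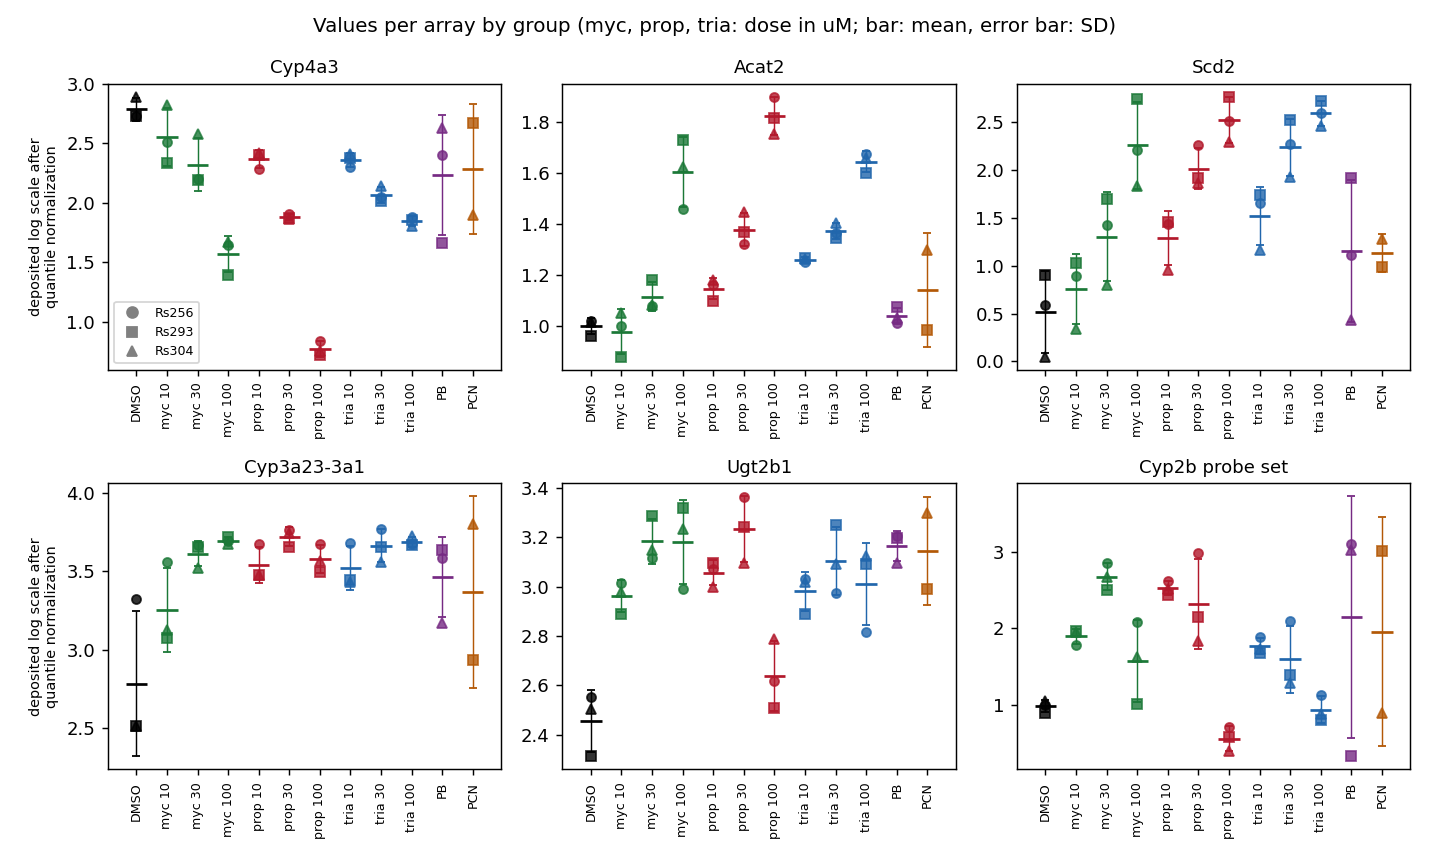
Values per array (y axes, deposited log scale after quantile normalization) of 5 genes and of the Cyp2b probe set in each group, with symbols for the Rs codes, a bar at the mean and error bars of 1 SD. Cyp4a3 falls by 2.01 from DMSO to 100 uM propiconazole; the Cyp2b probe set is high at 10 and 30 uM propiconazole and low at 100 uM.

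Compared directly at 100 uM, propiconazole differed from myclobutanil in single PPARalpha and NRF2 targets. Angptl4, Cyp4a3 and Eci1 were higher with myclobutanil by 0.89 (SE 0.162, adjusted p = 0.00649), 0.80 and 0.69, as was Cyp2c11 by 0.59. Gstp1 (-1.21), Sfn (-1.11, adjusted p = 0.00129), Fabp5 (-0.86) and Nqo1 (-0.73) were lower with myclobutanil. The PPARalpha list differed by a mean of 0.32 (95% interval 0.12 to 0.52; 2 members higher, 4 adjusted over the list alone); its call was lost with an estimated correlation (adjusted p = 0.0707). NRF2 targets differed by -0.29 (95% interval -0.55 to -0.03; 2 lower, 4 adjusted over the list alone), a call also lost (adjusted p = 0.23). Steroid metabolism and p53 targets (adjusted p = 0.0707 each), bile acid genes (adjusted p = 0.0831), AhR targets (adjusted p = 0.128), CAR targets (adjusted p = 0.278) and hepatocyte function (adjusted p = 0.505) were lost in the same way. For sterol synthesis the difference was -0.04 (95% interval -0.15 to 0.07).

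Myclobutanil was higher in 39 genes and lower in 39, and in 338 and 406 with the replicate block. On the values as deposited it was higher in 3 and lower in 13, and after median centring in 2 and 16. When only the 2 groups compared were fitted, limma called 0 of the 10490 genes, with 648 at an unadjusted p under 0.05. The total of 78 became 2 without Rs304 and 5 without Rs293. It was 31, 45 and 23 without the myclobutanil arrays of Rs293, Rs256 and Rs304, and 42 without the propiconazole array of Rs304. Of 10 named genes called, Sdcbp2 and Sfn remained called on the values as deposited, and limma called 7, 3 and 0 of the 10 without Rs256, Rs293 and Rs304.

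Against triadimefon at 100 uM, propiconazole had lower Cyp4a3 (-1.07, SE 0.172, adjusted p = 0.00254), Eci1 (-1.03), Angptl4 (-0.92) and Rarres2 (-0.76) and higher Sfn (0.91), Anpep (0.52) and Ddit3 (0.44). The PPARalpha list was lower by a mean of 0.44, written as a difference of -0.44 (95% interval -0.64 to -0.24; 4 of 21 members lower, 9 adjusted over the list alone; adjusted p = 0.0149 with an estimated correlation). AhR targets, fatty acid synthesis and steroid metabolism (adjusted p = 0.132 each), ribosomal proteins (adjusted p = 0.407), sterol synthesis and NRF2 targets (adjusted p = 0.428 each) were lost with an estimated correlation. Propiconazole was higher in 28 genes and lower in 25, and in 265 and 216 with the replicate block. On the values as deposited it was higher in 4 and lower in 3, and after median centring in 6 and 3. When only these 2 groups were fitted, limma called 6 (720 at an unadjusted p under 0.05), and with each probe set as a feature it called 90. The total of 53 became 0 without Rs304, 5 without Rs293 and 146 without Rs256, and lay between 16 and 22 without the propiconazole array of Rs304 (22) or Rs293 (18) or the triadimefon array of Rs293 (16) or Rs304 (18). Of 10 named genes called, Sfn remained called on the values as deposited, and limma called 9, 5 and 0 of the 10 without Rs256, Rs293 and Rs304.

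Between myclobutanil and triadimefon at 100 uM limma called 0 genes, with 200 at an unadjusted p under 0.05, and with the replicate block 1, the desaturase Fads2 (-0.40 in myclobutanil, blocked adjusted p = 0.0358). The intervals of the named genes were wide: Cyp4a3 differed by -0.28 (95% interval -0.63 to 0.08), Cyp3a23-3a1 by 0.01 (-0.36 to 0.37) and Acat2 by -0.04 (-0.17 to 0.09). The PPARalpha list differed by -0.12 (-0.32 to 0.08; adjusted p = 0.0361, and adjusted p = 0.59 with an estimated correlation) and sterol synthesis by 0.02 (-0.09 to 0.13). Bile acid genes, NRF2 targets and hepatocyte function at 100 uM were also called at the preset correlation alone, at adjusted p = 0.59 each when it was estimated. At 10 and 30 uM limma called 0 genes for every pair, with and without the replicate block. Unblocked, 5 to 220 genes had an unadjusted p under 0.05, where chance alone would give about 524. At 10 uM the sterol synthesis mean was lower with myclobutanil than with triadimefon by -0.17 (-0.28 to -0.06; adjusted p = 0.00021 with an estimated correlation). At 30 uM it was lower with myclobutanil than with propiconazole by -0.14 (-0.25 to -0.03; adjusted p = 0.0311 with an estimated correlation, and 0.0579 when the replicate block was added) and than with triadimefon by -0.17 (-0.28 to -0.06; adjusted p = 0.000647), and the propiconazole minus triadimefon difference was -0.03 (-0.14 to 0.08). Fatty acid synthesis was lower with myclobutanil than with triadimefon at 30 uM (median -0.08, mean -0.13, adjusted p = 0.0424 with an estimated correlation).

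Other list differences at 10 and 30 uM were called with the preset correlation and lost with an estimated one. For myclobutanil minus propiconazole at 10 uM these were PPARalpha targets (adjusted p = 0.882), sterol synthesis (adjusted p = 0.056), fatty acid synthesis (adjusted p = 0.0587) and ribosomal proteins (adjusted p = 0.352). At 30 uM they were PPARalpha targets (adjusted p = 0.759), fatty acid synthesis (adjusted p = 0.0522), NRF2 targets (adjusted p = 0.822) and ribosomal proteins (adjusted p = 0.0701). For myclobutanil minus triadimefon they were PPARalpha and NRF2 targets (adjusted p = 0.79 each) and fatty acid synthesis (adjusted p = 0.262) at 10 uM, and NRF2 targets (adjusted p = 0.532) and mitochondrial respiration (adjusted p = 0.791) at 30 uM. For propiconazole minus triadimefon they were sterol synthesis at 10 uM (adjusted p = 0.212) and ribosomal proteins at 30 uM (adjusted p = 0.749). The replicate block with an estimated correlation called fatty acid synthesis lower with myclobutanil than with propiconazole at 10 uM (adjusted p = 0.0335) and 30 uM (adjusted p = 0.0366), and NRF2 targets lower than with triadimefon at 30 uM (adjusted p = 0.0415).

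The genes called at 100 uM overlapped between triazoles. Myclobutanil and propiconazole shared 64 of the rises and 60 of the falls, where independent lists of these sizes would share 4.27 and 3.36. Propiconazole and triadimefon shared 81 and 93 (5.79 and 5.65 for independent lists), and myclobutanil and triadimefon 42 and 30 (0.581 and 0.578). The same DMSO arrays entered both sides. Across genes, which are not independent replicates, changes correlated at r = 0.839, 0.871 and 0.841 in the order given, where simulated unchanged groups sharing the DMSO arrays gave a mean r of 0.475, 0.463 and 0.497, with upper ends of the central 95% at 0.84, 0.853 and 0.868. The r of 0.839 and 0.841 lay within the simulated range of their pairs, and 0.871 lay above it. The covariances were 0.0198, 0.0216 and 0.0138 against simulated means of 0.002, 0.00205 and 0.00221. The simulated groups shared 0 called genes on average, but groups without a change are rarely called. Neither this count nor the independent lists thus measures how much overlap the shared DMSO arrays add.

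Phenobarbital at 200 uM raised Ugt2b1 by 0.71 (SE 0.0986, n = 3 and 3, adjusted p = 0.0014), the 1 gene called. The CAR target list rose (1 of 14 members, 2 adjusted over the list alone; median 0.06, mean 0.21, adjusted p = 0.0299 with an estimated correlation), as did PXR targets (1 of 9 adjusted over the list alone; median 0.20, adjusted p = 0.0299 with an estimated correlation), and PPARalpha targets fell as a list (median -0.23, adjusted p = 0.00776 with an estimated correlation). Cyp3a23-3a1 stood at 0.68 (SE 0.178, adjusted p = 1) and was higher in all 3 codes. A further 7 lists were called with the preset correlation and lost when it was estimated, at adjusted p between 0.158 and 0.348. Of these, NRF2 targets were called with both an estimated correlation and the replicate block (adjusted p = 0.0174). Phase II conjugation, called higher at the preset correlation, had a median of -0.01 and a mean of 0.08. With the replicate block 2 genes were called, Ugt2b1 and Cyp2c6v1, and limma called 0 on the values as deposited, after median centring and when only the 2 groups were fitted (47, 44 and 64 at an unadjusted p under 0.05). The 1 call was lost without Rs293 or without Rs304, and 2 genes were called without Rs256 or its DMSO array.

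PCN at 30 uM also raised Ugt2b1 (0.69, SE 0.11, n = 2 and 3, adjusted p = 0.0147), the 1 gene called, and with the replicate block Crp and Cyp2c6v1 as well. Cyp3a23-3a1, the main PXR target, stood at 0.58 (SE 0.199, adjusted p = 1). PCN had no Rs256 array while the DMSO mean included one, so unblocked PCN changes could also hold a difference between codes. For Cyp3a23-3a1 DMSO read 3.32 in Rs256 and 2.52 in Rs293 and Rs304. Against DMSO of the same code, the arrays labelled PCN were higher by 0.42 (Rs293) and 1.28 (Rs304). With the replicate block the hepatocyte function list was not called at the preset correlation (adjusted p = 0.145). Of 10 lists called, none remained with an estimated correlation: PXR targets (median 0.29) and CAR targets (0.10) each gave adjusted p = 0.179, as did sterol synthesis and phase II conjugation, while PPARalpha targets gave adjusted p = 0.193. Fatty acid synthesis gave adjusted p = 0.288, endoplasmic reticulum stress adjusted p = 0.317, hepatocyte function adjusted p = 0.433 and NRF2 targets adjusted p = 0.482. In the fit with the replicate block PXR, CAR and NRF2 targets gave adjusted p = 0.0295 each with an estimated correlation. Steroid metabolism, called higher at the preset correlation, had a median of 0.01 and a mean of -0.00, and its adjusted p was 0.317 with an estimated correlation. Limma called 0 genes on the values as deposited, after median centring and when only the 2 groups were fitted (73, 93 and 359 at an unadjusted p under 0.05), and 0 without Rs304, without the PCN array of Rs304 or without the DMSO array of Rs293 or Rs304; it called 2 without Rs256 and 4 without Rs293, which left a lone PCN array assumed to vary like the other groups.

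Directions for phenobarbital and PCN rest on arrays whose labels did not run alike. The phenobarbital minus PCN difference correlated at r = -0.656 across genes between Rs293 and Rs304, while 45 pairs of the other groups gave a median of 0.395 and a lowest value of -0.172. On the Cyp2b probe set, which the annotation assigns to no single gene, the arrays labelled phenobarbital read 3.10 (Rs256), 0.32 (Rs293) and 3.03 (Rs304), those labelled PCN 3.02 (Rs293) and 0.89 (Rs304), and DMSO 0.98 (SD 0.0807, n = 3). Without both Rs293 arrays limma called 1 gene for phenobarbital and, with a lone PCN array, 4 for PCN. With the replicate block as well it called 2 and 133.

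**Figure D4:**
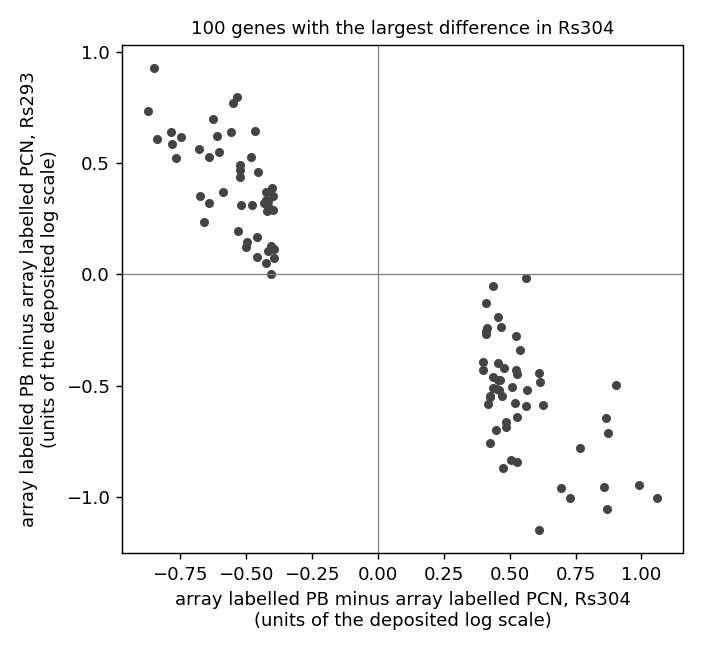
Difference between the array labelled phenobarbital and the array labelled PCN in Rs304 (x axis) against the same difference in Rs293 (y axis), in units of the deposited log scale after quantile normalization, for the 100 genes with the largest difference in Rs304, which were picked by that difference. All 100 have the opposite sign in Rs293.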

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

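The tests on the phenobarbital and PCN labels, on the Cyp2b probe set, and on normalization and hepatocyte share as sources of the PPARalpha change were chosen only after the results they measure had been seen.

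The array labelled phenobarbital of Rs293 and the array labelled PCN of Rs293 stood apart from their groups: the phenobarbital minus PCN difference correlated at r = -0.656 across genes between Rs293 and Rs304. In the array labelled phenobarbital of Rs293 the PXR list mean lay 0.46 above DMSO of the same code (SD of such a difference 0.132). It lay 0.127 and 0.146 above DMSO in phenobarbital of Rs256 and Rs304, and 0.53 in PCN of Rs304. If that array of Rs293 did hold phenobarbital, its value argues against a general lack of response to phenobarbital in the Rs293 cells. A lack confined to Cyp2b would stay open for it. If the array held PCN, its value says nothing about a response to phenobarbital. An exchange of both labels may explain the pattern, and so may a single wrong array, and these cannot be told apart here: on the Cyp2b probe set the array labelled PCN of Rs293 lay 2.13 above PCN of Rs304 (largest such gap in another group 0.619) and its PXR list mean only 0.1 above DMSO, which favour an exchange, while its r across genes with phenobarbital of Rs304 minus that with PCN of Rs304 was -0.0372, which does not. After the triazole mean of each code was removed, the same array had r = 0.377 with phenobarbital of Rs304, -0.114 with phenobarbital of Rs256 and 0.0452 with PCN of Rs304, and the array labelled phenobarbital of Rs293 had -0.239, -0.537 and 0.398, where the phenobarbital arrays of Rs256 and Rs304 gave 0.451. Before that mean was removed, the array labelled phenobarbital of Rs293 had r = 0.761 with PCN of Rs304 and 0.293 with phenobarbital of Rs304. No label was changed.

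The Cyp2b probe set, outside the gene-level comparisons because it names no single gene, had a propiconazole dose slope of -2.00 units per log10 step (SE 0.491, adjusted p = 0.0109, and 0.00219 with the replicate block), with group means of 2.53, 2.32 and 0.55 at 10, 30 and 100 uM and 0.98 in DMSO. Means at the same doses were 1.90, 2.68 and 1.57 with myclobutanil and 1.77, 1.59 and 0.93 with triadimefon. Their dose slopes were not called (adjusted p = 0.882 and adjusted p = 0.752). Arrays of 100 uM that were in truth not exposed are argued against by the PPARalpha list, whose highest mean among the 3 was 0.762 (SD 0.0146), below the 1.53 of the lowest DMSO array. A general loss of hepatocyte transcripts is argued against by the hepatocyte function list without Alb, whose median moved by -0.103 from 30 to 100 uM while the probe set moved by -1.77. Transcripts of more than 1 Cyp2b gene may share this probe set, and that stays open, as does an effect of dose. No change of it against DMSO passed the test, but its SE came from a spread shared by all groups. That spread took in the groups labelled phenobarbital (SD 1.59) and PCN (SD 1.51), whose labels are in doubt. At 10 uM propiconazole the 3 arrays read 2.44 to 2.63, against 0.894 to 1.05 in DMSO. The lack of a call thus does not show a lack of change.

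PPARalpha targets fell as a list at 100 uM of each triazole, with a median of -0.943 for propiconazole. RNA quality as the whole cause is argued against by a median of -0.808 with the Actb difference as covariate (14 of 21 members called), a test chosen before. The quantile normalization as the whole cause is argued against by a median of -0.912 on the values as deposited. The authors' own processing, which is not stated, lies under both sets of values, so its part was not tested. A lower share of hepatocytes as the whole cause is argued against because 1 of 24 hepatocyte function genes fell as far (median -0.16). Alb, which the normalization fixed, was left out. A smaller loss of hepatocytes would not reach that bar, so a part in the change stays open. An effect of the compounds may remain as a hypothesis; cell loss and culture differences between groups were not measured.

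The dose slope differed between propiconazole and triadimefon for 2 genes by a test of the difference itself, Fgr (-0.458) and Rarres2 (-0.839), and for 82 with the replicate block. Between myclobutanil and propiconazole limma called 0 slope differences (560 at an unadjusted p under 0.05, and 115 called with the block), and between myclobutanil and triadimefon 0 (60 unadjusted, 0 with the block). Of 3737 probe sets that name no gene or several and were left out of the gene fit, 21 were called for myclobutanil, 349 for propiconazole and 48 for triadimefon at 100 uM, and 1 for triadimefon at 30 uM. For the pairs at 100 uM 15 (myclobutanil minus propiconazole) and 12 (propiconazole minus triadimefon) were called, and for the slopes 5, 228 and 2 in the order myclobutanil, propiconazole, triadimefon. Groups of 3 arrays were not tested for arrays far from the others.

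For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Against DMSO the real counts were 0, 1 and 127 for myclobutanil, 1, 4 and 1255 for propiconazole and 0, 3 and 192 for triadimefon at 10, 30 and 100 uM and 1 for phenobarbital, and the highest other split gave 0 in each. For the pairs at 100 uM the real counts of 78, 53 and 0 (myclobutanil minus propiconazole, propiconazole minus triadimefon, myclobutanil minus triadimefon) stood beside highest others of 1, 9 and 0, and for the pairs at 10 and 30 uM all were 0. For the slopes, a share of splits under 0.05 called as many genes as the real one for propiconazole and triadimefon. For propiconazole 1 of 100 did, the real one itself (real 916, highest other 902, or 715 among splits within codes). For triadimefon 1 of 100 did, again the real one (real 8, highest other 0, or 3 within codes). The propiconazole split of 902 kept the 3 arrays of 100 uM together at the low end. A count near the real one thus arose without the true order of doses. The 8 triadimefon genes were not called on the values as deposited or without Rs304. For myclobutanil 5 of 100 splits called as many as the real 26, so chance was not excluded over splits that ignore the code. The highest called 473, with Rs256 arrays at the high and Rs293 arrays at the low end, which points to a structure by code. Among 99 other splits within codes, which keep that structure out, the highest called 12, below the real 26.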

How the results depend on the processing

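The settings that leave out the Rs293 arrays labelled phenobarbital and PCN, and the block on the values as deposited, were chosen after seeing the data. No count against DMSO, between triazoles or of slopes moved over 1.5 times with trend and robust on, with the mean above the overall median as filter, or with the mean of a gene's probe sets. The causes were not tested. Alternatives for linear values did not apply, as the values were log-like, and were not run. Treatments below run myclobutanil, propiconazole, triadimefon at 10, 30, 100 uM, then phenobarbital and PCN.

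Under the replicate block, counts against DMSO were 1, 2, 1041; 2, 275, 3075; 1, 110, 1239; 2 and 3. Pairs at 100 uM gave 744 (myclobutanil minus propiconazole), 1 (myclobutanil minus triadimefon) and 481, slopes 696, 2602 and 307. Genes shared by 2 treatments were 934 (myclobutanil and propiconazole), 702 (myclobutanil and triadimefon) and 1104; with phenobarbital 2, 1 and 2, with PCN 3, 1 and 2. As deposited, the counts became 0 and 8 for myclobutanil at 30 and 100 uM, 0, 2 and 428 for propiconazole, 0 and 14 for triadimefon at 30 and 100 uM, and 0 for phenobarbital and PCN; pairs 16 and 7; slopes 2, 264 and 0; shared genes 8, 6 and 13, and 0 with phenobarbital or PCN; lists called 5 for propiconazole and 5 for PCN. Median centring gave 0 and 9, 0, 2 and 501, 0 and 17, 0 and 0, pairs 18 and 9, slopes 2, 279 and 0, and 5 lists for PCN. Fits of only the groups compared gave 0 and 1, 0, 1 and 542, 0 and 10, 0 and 0, pairs 0 and 6, and slopes 0 and 365. Each probe set as a feature gave 2 and 2034 for propiconazole at 30 and 100 uM, 5 for triadimefon at 30 uM, 90 for propiconazole minus triadimefon and 1427 for the propiconazole slope; no filter gave 2 for propiconazole at 30 uM. An estimated correlation left 2 lists for each triazole at 100 uM, 3 for phenobarbital and 0 for PCN. The block on the values as deposited gave 0 for myclobutanil at 30 uM, propiconazole at 10 uM, phenobarbital and PCN, and 138 for propiconazole at 30 uM. Without the Rs293 arrays labelled phenobarbital and PCN the counts were 4 for PCN, 20 for propiconazole and 13 for triadimefon at 30 uM, and slopes 63 and 14 for myclobutanil and triadimefon; with the block too, 1, 35, 1192; 8, 431, 3209; 10, 327, 1396; 2 and 133.

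Leaving out 1 code or array gave 0 to 2 and 16 to 133 for myclobutanil at 30 and 100 uM, 0 to 2, 0 to 6 and 391 to 1487 for propiconazole, 0 to 1, 0 to 2 and 11 to 123 for triadimefon, 0 to 2 for phenobarbital and 0 to 4 for PCN. Pairs ranged from 2 to 100 and 0 to 146, slopes from 1 to 89, 206 to 1233 and 0 to 5, and lists for PCN from 5 to 10. The Actb difference ranged from -0.11 to 0.00257 (myclobutanil), -0.167 to -0.0893 (propiconazole), 0.046 to 0.132 (triadimefon) and -0.124 to -0.0487 (phenobarbital).

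Directions turned as follows, given as changes of genes and as mean changes of lists; for a list the test direction turned, and its mean may keep its sign. Replicate block: Cyp51 -0.0036 and Cyp1a1 0.0527 (PCN). As deposited: mitochondrial respiration 0.0715 and Cyp51 0.119 (phenobarbital), Hp 0.0268 and Cyp1a1 0.138 (triadimefon), Cyp1a1 0.128 (PCN). Median centring: ribosomal proteins 0.0582 (propiconazole), mitochondrial respiration 0.0646 and Cyp51 0.112 (phenobarbital), Hp 0.0206 and Cyp1a1 0.131 (triadimefon), Cyp1a1 0.127 (PCN). Mean of probe sets: Cyp51 0.00402 (phenobarbital). Without the Rs293 arrays labelled phenobarbital and PCN: hepatocyte function 0.0105, mitochondrial respiration -0.00743 and Cyp51 0.0342 (phenobarbital), Cyp7a1 -0.381 (PCN). Leaving out 1 code gave, for PCN, PXR targets -0.0264 to 0.447, PPARalpha targets -0.362 to -0.0232, NRF2 targets -0.0655 to 0.155, endoplasmic reticulum stress -0.0297 to 0.0931, Cyp7a1 -0.411 to 0.621, Cyp51 -0.0400 to 0.158 and Cyp1a1 -0.116 to 0.0814. It gave Cyp7a1 -0.0774 to 0.282 (myclobutanil) and -0.282 to 0.067 (propiconazole), Cyp1a1 -0.0656 to 0.0539 (triadimefon) and -0.0282 to 0.0832 (phenobarbital), and Cyp51 -0.0608 to 0.0921 (phenobarbital). Of these genes Hp alone was called.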

Other observations

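The 7 lists below were chosen after some of the genes had been seen, so their tests are not independent of the data. Enzymes of fatty acid beta-oxidation, none of them on the earlier lists, fell at 100 uM: 19 of 24 with propiconazole (median -0.49, adjusted p = 0.000139 with an estimated correlation), 8 with myclobutanil (-0.28, adjusted p = 0.000295) and 5 with triadimefon (-0.24, adjusted p = 0.00146). With propiconazole Decr1 fell by 1.11, Ech1 by 1.05, Hadh by 0.91 and Acaa2 by 0.80. The list was also lower with phenobarbital (-0.09, adjusted p = 0.0106), and with PCN its call was lost with an estimated correlation (median -0.11, adjusted p = 0.24). With the replicate block the beta-oxidation falls numbered 16 with myclobutanil, 22 with propiconazole and 16 with triadimefon. Complement and coagulation genes fell with propiconazole (6 of 24, median -0.29, adjusted p = 0.0367), among them F9 (-0.86), C8b (-0.70) and F12 (-0.66), and with triadimefon (3 of 24, -0.17, adjusted p = 0.0375), while with myclobutanil the call was lost (-0.15, adjusted p = 0.1). In this list the replicate block called 9 lower and 1 higher with myclobutanil, 18 and 1 with propiconazole, and 9 lower with triadimefon.

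The other 5 added lists were not called at 100 uM with an estimated correlation. In the order myclobutanil, propiconazole, triadimefon, glycolysis and gluconeogenesis had medians of 0.14, 0.09 and 0.12 (adjusted p = 0.178, 0.612 and 0.531) and amino acid catabolism -0.04, -0.08 and -0.12 (0.617, 0.612 and 0.531). Cytoskeleton genes had -0.05, 0.00 and -0.01 (0.617, 0.858 and 0.964), lysosome 0.10, 0.20 and 0.09 (0.535, 0.493 and 0.531) and proteasome 0.05, 0.07 and 0.04 (0.617, 0.657 and 0.882). With propiconazole 6 lysosome genes rose and 1 fell, 7 amino acid genes fell (Bckdha, Fah, Gnmt, Haao, Kynu, Otc and Prodh) and Bcat2 rose. Of the glycolysis list Aldoa, Aldoc, Eno2 and Pck2 rose, and of the cytoskeleton list Lgals3 and Tubb6. With myclobutanil 1 lysosome gene rose and with triadimefon 2 amino acid genes fell. Calls in these 5 lists were more with the replicate block. In the order myclobutanil, propiconazole, triadimefon, it called 8, 14 and 8 lysosome genes higher (1 and 2 lower with the first 2 compounds) and 7, 6 and 4 glycolysis genes higher (1 and 2 lower). Of the amino acid list it called 6, 11 and 8 lower and 4, 5 and 3 higher, and of the cytoskeleton list 1, 4 and 2 higher (1 and 3 lower). Of the proteasome list it called Psmd2 higher with myclobutanil and, with propiconazole, Psmc4 and Psmd2 higher and Psma3 and Psma6 lower.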
